A study of Homo sapiens with 10 samples.

How the data were processed

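RNA of NGP neuroblastoma cells had been hybridised, per the labels, to one-colour (Cy3) Agilent arrays 10 days after infection with a lentiviral empty vector (control, n = 4) or with a hairpin against EED (shEED-1, n = 3; shEED-2, n = 3). The deposited scanner tables held, per the file headers, background-subtracted and detrended spot intensity on a linear scale (gProcessedSignal), median spot and background intensity, and quality calls, written by Feature Extraction 12.1.1.1; the submitters' processing notes name version 9.1. The deposited matrix of intensity equalled gProcessedSignal at all 62976 features and had no scaling between arrays. Arrays of the design had 62976 features, of which 58717 were not controls.

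Signals were put on the log2 scale and each array's 75th percentile over non-control spots was subtracted. Spots called non-uniform or population outliers were left out (230 to 298 per array; 0 saturated), and replicate spots of a probe were averaged. Gene symbols came from the accession printed for each probe, matched without its version to the RefSeq table of assembly GRCh38.p14, which was used for names only; the array grid was built on another assembly, so no coordinates are given. Of 50599 probes, 33346 had 1 symbol, 0 several and 17253 none; probes without a symbol were tested under their accession and are not named. Probes well above background on every array of at least 1 group were kept (22771), and each gene was represented by its brightest probe over all arrays (17779 genes). The median within-group SD was 0.094 on the log2 scale.

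One linear model with a mean per group was fitted to all 10 arrays with limma 3.58.1 (lmFit and eBayes, 9.13 degrees of freedom) in R 4.3.3, with the data.table package (version 1.17.8), for shEED-1 against control, shEED-2 against control and shEED-2 against shEED-1. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes within a comparison, and an adjusted p below 0.05 passed. A gene counted as shared if it passed under both hairpins with the same sign. Of 24 gene lists (588 genes, 579 on the array, 436 measured), the 23 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, and also with an estimated correlation and with fry. The lists were PRC2 components, PRC1 components, genes repressed by EZH2 in neuroblastoma, HOX genes, non-HOX developmental regulators bound by Polycomb in stem cells, adrenergic regulators, mesenchymal markers, catecholamine and chromaffin genes, neuronal structure genes, synaptic genes, neurotrophin and GDNF receptors, cell cycle genes, CDK inhibitors, p53 targets, the BCL2 family and caspases, MYC and MYCN targets, interferon-stimulated genes, antigen presentation, the unfolded protein and integrated stress response, cholesterol synthesis, hypoxia and glycolysis, Schwann cell and melanocyte markers, fibroblast and matrix markers, and blood and endothelial markers.

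Groups, comparisons, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule named each measured PRC2 subunit; the 12 largest rises and 12 largest falls by the mean of both hairpins among genes that passed in both with 1 sign, with a symbol and well above background on every array of the higher group; up to 4 members per list with the largest mean change among those that passed in both (else up to 2 that passed in 1, else the 2 brightest); NGFR, CASZ1, CLU, RUNX3, MYCN, MDM2 and CDKN1A; and the 8 highest and 8 lowest in shEED-2 against shEED-1. It gave 130 genes, and 50 more were added after their values were seen; some genes that the rule gave are not reported here. Of these 180 genes, 37 had several kept probes, and those of ATF3 and CBX7 opposed each other under shEED-2.

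On simulated data, 17779 genes with the residual spread of these arrays and 200 changed genes in each of 3 simulations, the fit recovered 25.3%, 59.3%, 87.3% and 98% of log2 changes of 0.25, 0.5, 1 and 2 in shEED-1 and 18.7%, 60%, 87.3% and 99.3% in shEED-2, with at most 12 false calls. In the data 10403 and 7096 genes passed, and the Benjamini-Hochberg cut-off depends on the share of changed genes. The simulated recovery and count of false calls therefore do not carry over to the data. Alternatives were quantile normalization, a shift to equal medians, no filter on dim probes, probes well above background on all arrays, the mean of a gene's probes, every probe tested, the matrix values, an intensity trend with robust variance, array quality weights, a fit of only the compared groups, slide as a fixed block (slide and scan coincided), a replicate block, a 2-fold minimum, and each array left out. Added after the files were seen were a shift by 7 spike-in probes, normexp background correction (offset 50) of the median signals, because the tables used held no mean signals as planned, and the arrays of slide 1 alone. Spike-in signal was 0.25 higher (log2) in knockdown than in control arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No array was left out of the model, and no sequence, protein or histone mark data were part of the series used here.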

Results

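RNA from NGP cells, a neuroblastoma cell line with amplified MYCN, was measured on 10 one-colour arrays 10 days after lentiviral infection. The empty-vector control had 4 arrays, the first hairpin against EED (shEED-1) 3 and the second (shEED-2) 3. The array number limits precision. The 75th-percentile signal was 143.6 to 158.2 in control arrays and 163.4 to 189.8 in knockdown arrays, and 47.1% to 49.7% of spots were well above background. The 8 arrays of slide 1 were control replicates 1 and 2 and every knockdown array, and control replicates 3 and 4 were on slide 2. Slide 1 alone and slide as a block therefore gave the same changes of a given probe. Neither could move the changes of shEED-2 against shEED-1, only the calls. Correlations across genes, which are not independent replicates, were 0.9955 to 0.9971 within groups, 0.9776 to 0.9793 between control and shEED-1, and 0.9882 to 0.9891 between control and shEED-2. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Of 17779 genes tested, 14070 had a symbol. Changes are log2 fold changes with the standard error (SE) from limma; genes passed at a Benjamini-Hochberg adjusted p below 0.05, and lists at an adjusted p below 0.05 in limma's camera test. Paired values give shEED-1 first and shEED-2 next, with one SE because both hairpins had equal arrays, and a named value passed unless its p is given.

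EED, the PRC2 subunit that binds trimethylated histone H3 lysine 27 and is needed for the methyltransferase activity of EZH2, was lower in every knockdown array than in every control array. Its log2 level relative to the array's 75th percentile was 3.73, 3.78, 3.77 and 3.91 in the control arrays, 1.92, 2.02 and 1.90 under shEED-1 and 2.46, 2.49 and 2.42 under shEED-2. The mean fell from 3.80 ± 0.0788 (SD, n = 4) to 1.95 ± 0.0628 (SD, n = 3) and 2.46 ± 0.0353 (SD, n = 3). These were changes of -1.85 ± 0.0536 (limma adjusted p 1.78e-08), leaving 27.7% of the control level, and -1.34 ± 0.0536 (limma adjusted p 3.61e-07), leaving 39.4%. The transcript was lower under shEED-1 than under shEED-2, by a difference of 0.51 ± 0.0573 (adjusted p 7.62e-05). On slide 1 alone, and with slide as a block, the changes were -1.81 and -1.30. EED was measured by 1 probe, and no protein or histone mark data were part of the series used here.

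Among the other PRC2 subunits, EZH1, the second methyltransferase of the complex, rose under both hairpins (0.38 and 0.42, SE 0.0498), and the histone-binding subunit RBBP7 fell under both (-0.45 and -0.34, SE 0.0535). EZH2, the main methyltransferase, did not pass under shEED-1 (0.05, adjusted p 0.468; 0.16, adjusted p 0.048, with quantile normalization) or shEED-2 (0.01, adjusted p 0.902). SUZ12, a core subunit, fell by 0.29 under shEED-1 (adjusted p 0.000118) and had a value of -0.10 under shEED-2 (adjusted p 0.0552). The accessory subunits AEBP2 (-0.32) and JARID2 (-0.17) also fell under shEED-1, and their values under shEED-2 were -0.07 (adjusted p 0.441) and -0.10 (adjusted p 0.0607). PHF19, which binds methylated lysine 36 of histone H3, fell under shEED-2 (-0.37) but not under shEED-1 (0.04, adjusted p 0.53; difference -0.41 ± 0.0589). EPOP rose under both (0.21 and 0.42, SE 0.0495), its shEED-1 call being lost on slide 1 alone (0.17, adjusted p 0.05). MTF2 was at 0.07 (adjusted p 0.613) and -0.09 (adjusted p 0.551), and passed under shEED-1 without shEED-1 replicate 3 (0.22, adjusted p 0.011). Under shEED-1, PHF1 (0.19) rose and RBBP4 (-0.32) fell, but PHF1's call was lost without any of control replicates 3 and 4 and shEED-1 replicates 1 and 3 (0.14 to 0.18), and RBBP4's without any of control replicates 1, 3 and 4 and shEED-1 replicate 3 (-0.30 to -0.18). Both were lost with slide as a block. Of RBBP4's 3 other probes, 2 fell under both hairpins (-0.40 and -0.28, and -0.35 and -0.27) and 1 passed under neither. In the text on lists that did not pass, a range after a median spans all alternatives and is given where its sign turned or its size moved at least 1.5-fold. Under shEED-1, of 12 PRC2 genes, 3 rose and 6 fell (median -0.066, range -0.11 to -0.00597, adjusted p 0.53). Under shEED-2, of 12 PRC2 genes, 2 rose and 3 fell, 2 and 5 adjusted over the list alone (median -0.093, range -0.14 to 0.031, adjusted p 0.35).

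**Figure D1:**
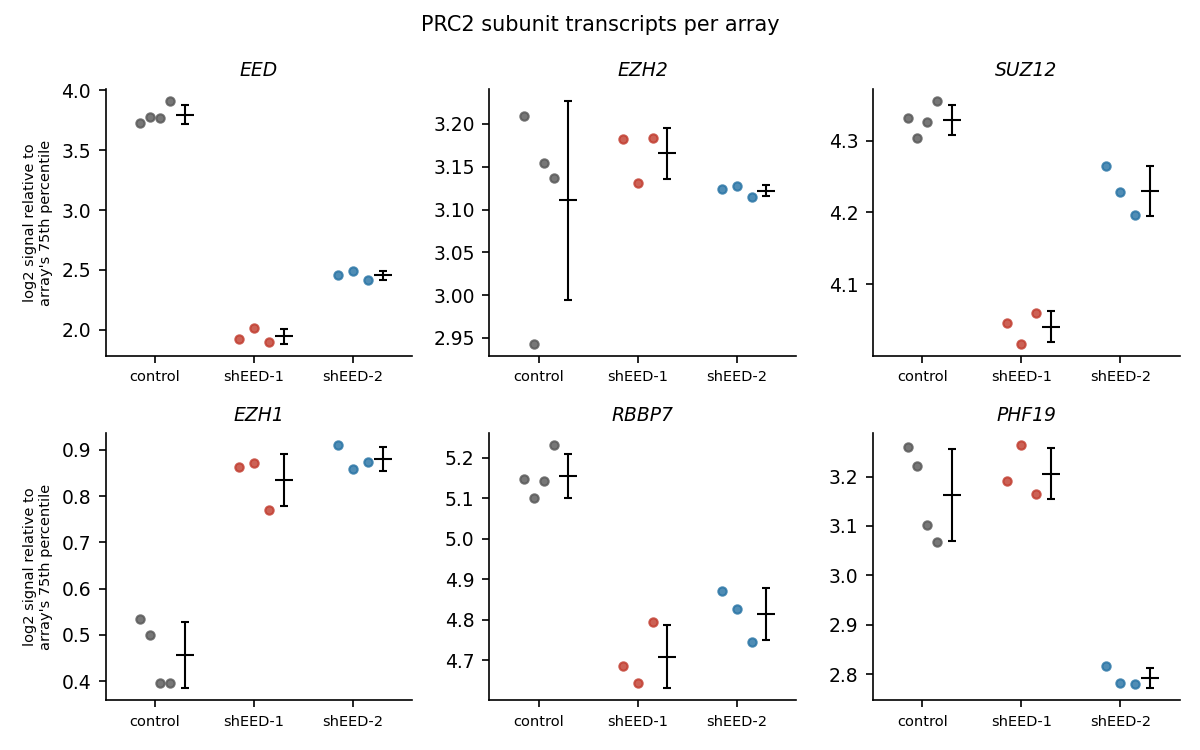
Log2 signal of 6 PRC2 subunit transcripts relative to the array's 75th percentile in control (n = 4), shEED-1 (n = 3) and shEED-2 (n = 3) arrays; points are arrays, and the bar beside them is the mean ± SD. EED was lower in all 6 knockdown arrays, with means of 3.80, 1.95 and 2.46.

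The comparison of shEED-1 with the control asked which transcripts changed when this hairpin lowered EED. Of the lists that rose, only synaptic genes also passed with an estimated correlation (adjusted p = 0.0098 with an estimated correlation). Among single genes, STMN4, a microtubule regulator of the stathmin family, rose by 5.80 ± 0.0912 on the log2 scale (n = 3 against 4 arrays, limma adjusted p 9.5e-10), and NGFR, the low-affinity nerve growth factor receptor, by 4.23 ± 0.163 (limma adjusted p 7.88e-08). DBH, which makes noradrenaline from dopamine, fell by 1.92 (SE 0.0497, adjusted p 1.08e-08), and 25 of 34 cell cycle genes fell (adjusted p = 0.11 for the list with an estimated correlation). In total 10403 genes passed (58.5%), 5133 higher and 5270 lower, with a median absolute change of 0.42, and 1115 passed with at least a 2-fold change, 732 higher and 383 lower. On slide 1 alone 9046 passed, and 9319 with slide as a block.

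Of 23 synaptic genes measured, 21 rose, 1 fell and 1 did not pass (median 0.73, adjusted p 2.9e-07; adjusted p = 0.0098 with an estimated correlation). RAB3A, a GTPase of synaptic vesicle release, rose by 1.65 ± 0.0527, the vesicle proteins SYT11 and SYT4 by 1.49 ± 0.044 and 1.01 ± 0.0658, and the presynaptic adhesion gene NRXN2 by 2.36 ± 0.137. SYT1, the calcium sensor of fast release, was the member that fell (-0.39), a call lost with the mean of its probes (-0.22). Of 25 neuronal structure genes, 20 rose, none fell and 5 did not pass (median 0.35, adjusted p 2.9e-07; adjusted p = 0.13 with an estimated correlation). Beside STMN4, the glycolytic enzyme of neurons ENO2 rose by 1.42 ± 0.0629, the tau gene MAPT by 1.28 ± 0.0422, the adhesion gene L1CAM by 1.17 ± 0.0958 and DCX, a microtubule protein of migrating neurons, by 0.95 ± 0.0545. ELAVL4, an RNA-binding protein of neurons, was at 0.04 (adjusted p 0.624), and passed with quantile normalization. List medians on slide 1 alone, equal to those with slide as a block, were 0.73 and 0.34. With background correction by normexp, which shrinks dim signals, the changes of STMN4 (3.63), NRXN2 (1.35) and L1CAM (0.57) were smaller. NRXN2, SYT1, L1CAM, DCX and ELAVL4 were chosen after their values were seen.

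Genes reported to be repressed by EZH2 in neuroblastoma mostly rose: of 9 measured, 7 rose, CDKN2A fell and CASZ1 did not pass (median 0.66, adjusted p 0.024). Adjusted p = 0.17 with an estimated correlation, and the call was also lost with quantile normalization (adjusted p 0.052), the mean of a gene's probes (0.052) and every probe tested (0.17). With normexp the list passed with a smaller median (0.2). Beside NGFR, the chaperone gene CLU rose by 0.66 ± 0.0942, the transcription factor RUNX3 by 0.23 ± 0.0578 (0.16 and not passing on another probe) and the CDK inhibitor CDKN1C by 0.89 ± 0.0716. CDKN1A, the p21 CDK inhibitor, rose by 1.54 ± 0.173 but was well above background on 1 of 4 control arrays, and KLF4, a transcription factor, by 0.59 ± 0.142, and normexp ended both calls (0.10 and 0.11). CDKN2A, another CDK inhibitor, chosen after its values were seen, fell by 0.66 (SE 0.0559), and the transcription factor CASZ1 was at 0.07 (adjusted p 0.323). Other lists held 5 of the 9 genes. The neurotrophin and GDNF receptors split, with NGFR, GFRA1 (0.53) and SORT1 (0.20) rising and RET (-1.74), NTRK3 (-0.71), NTRK2 (-0.39) and GFRA2 (-0.23) falling. Their median was -0.018, range -0.23 to 0.083, their mean 0.34, and the test pointed up (adjusted p 0.98). SORT1's call was lost without any of control replicates 2, 3 and 4 and shEED-1 replicates 1 and 2 (0.15 to 0.20), NTRK2's without shEED-1 replicate 1 or 3 (-0.37 to -0.33) and GFRA2's with quantile normalization (-0.07); GFRA1 and SORT1 were chosen after their values were seen. Slide 1 medians were 0.68 for the genes repressed by EZH2 and -0.045 for the receptors.

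Proliferation genes mostly fell. Of 34 cell cycle genes, 25 fell (26 adjusted over the list alone), 4 rose and 5 did not pass (median -0.34, adjusted p 1.3e-05; adjusted p = 0.11 with an estimated correlation). The mitotic kinase AURKA fell by 0.73 (SE 0.0576), the cyclin-dependent kinase CDK1 by 0.69 (SE 0.0364; -0.14 and not passing on another probe), TOP2A, a topoisomerase, by 0.52 (SE 0.0431) and cyclin B1 (CCNB1) by 0.42 (SE 0.0358). The 4 that rose act before or at the start of S phase: cyclin E1 (CCNE1, 0.37 ± 0.0601), the transcription factors E2F1 (0.22 ± 0.0523) and E2F2 (0.32 ± 0.0711) and the replication licensing factor CDT1 (0.20 ± 0.0442). Of 14 S-phase genes, a list chosen after the results were seen, 4 rose and 8 fell (median -0.21). MKI67, a proliferation marker, was at -0.01 (adjusted p 0.899) on its brightest probe, 1 of its other 2 probes did not pass either (0.10) and the last fell (-0.30). Of 29 MYC and MYCN targets, 17 fell, PPRC1 rose (0.17 ± 0.0426) and 11 did not pass (median -0.17, adjusted p 0.0077; adjusted p = 0.23 with an estimated correlation). Fallen members included the ribosomal RNA modification factor DKC1 (-0.50; -0.42 and not passing on another probe), LDHA (-0.52) and NME1 (-0.41), whereas MYCN itself was at 0.02 (adjusted p 0.708; it passed with quantile normalization). With quantile normalization the cell cycle median was -0.22. The MYC call was lost with quantile normalization (median -0.063, adjusted p 0.36) and normexp (0.09). Slide 1 medians were -0.37 and -0.22; CDK1, CCNB1, E2F1, E2F2, CDT1, MKI67 and PPRC1 were chosen after their values were seen.

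Of 19 mesenchymal neuroblastoma markers, 12 fell, 4 rose and 3 did not pass (median -0.3, adjusted p 0.021; adjusted p = 0.23 with an estimated correlation). SOX9 (-1.62 ± 0.157), SMAD3 (-1.51 ± 0.0676) and SNAI2 (-1.18 ± 0.0575), which encode transcription factors of mesenchymal and transforming growth factor beta programmes, fell, as did the matrix gene SPARC (-1.53 ± 0.0619) and the transcription factor PRRX1 (-0.71 ± 0.0537). The call was lost with quantile normalization (adjusted p 0.052), without a filter on dim probes (0.059) and with every probe tested (0.17), and the median was -0.18 with normexp. SOX9, SMAD3 and PRRX1 were chosen after their values were seen, and the list median on slide 1 was -0.33.

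The other lists did not pass under shEED-1, although many of their genes did. Of 24 HOX genes, 7 rose and 6 fell (median 0.02, range -0.1 to 0.08, adjusted p 0.98). Their mean was -0.15 and the test pointed up. HOXC13 was at least 1.67-fold lower and HOXD8 fell (-0.68 ± 0.0658). Of 45 non-HOX regulators bound by Polycomb in stem cells, 11 rose and 15 fell (median -0.057, range -0.16 to -0.018, adjusted p 0.6). The neurogenic factor NEUROD1 (1.96 ± 0.0458) and LHX1 (1.74 ± 0.0743) rose, and FOXF1 (-1.39 ± 0.0427) and PAX7 (at least 2.88-fold) were lower. Among PRC1 genes, CBX7, which binds the mark made by PRC2, rose (1.04 ± 0.0734; 0.68 with the mean of its probes). Of 21 PRC1 genes, 6 rose and 6 fell (median 0.13, range -0.038 to 0.16, adjusted p 0.6). Of 23 adrenergic regulators, 8 rose and 6 fell (median 0.015, range -0.017 to 0.14, adjusted p 0.92). GATA3, a regulator of sympathetic neurons, rose (0.37 ± 0.0501), and HAND2, another, was at -0.04 (adjusted p 0.587); it and GATA3 were chosen after their values were seen. Of 15 catecholamine genes, 2 rose and 6 fell (median -0.2, range -0.22 to -0.093, adjusted p 0.28), with falls of the vesicle cytochrome CYB561 (-1.48 ± 0.105) and the monoamine oxidase MAOA (-0.63 ± 0.0579).

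Apoptosis and stress genes moved both ways. BBC3 (1.92 ± 0.0567) and HRK (1.51 ± 0.0705), which encode killer proteins of the BH3-only class, rose, whereas the executioner caspase CASP6 (-0.98 ± 0.0424) and the survival gene BCL2 (-0.75 ± 0.0739) fell. CASP6 and BCL2 were chosen after their values were seen. Of 21 BCL2 family and caspase genes, 5 rose and 8 fell (median -0.01, range -0.049 to 0.046, adjusted p 0.72); the mean was 0.0094 and the test pointed down. Of 25 p53 targets, 11 rose and 5 fell (median 0.1, range 0.00365 to 0.14, adjusted p 0.14). SESN2 (1.46 ± 0.0709), TP53INP1 (1.25 ± 0.0765), BTG2 (1.37 ± 0.0462) and MDM2 (0.27 ± 0.0403), the last of which encodes the ubiquitin ligase of p53, rose. On other MDM2 probes the values were 0.48 and 0.42, which passed, and 0.01, which did not. Of 7 CDK inhibitors, 4 rose and 2 fell (median 0.31, range -0.046 to 0.6, adjusted p 0.53). Of 23 unfolded protein and integrated stress response genes, 11 rose and 6 fell (median 0.23, range 0.14 to 0.26, adjusted p 0.27), among them CHAC1 (0.91 ± 0.0447). Of 23 cholesterol synthesis genes, 6 rose and 12 fell, 6 and 13 adjusted over the list alone (median -0.19, range -0.26 to -0.12, adjusted p 0.14). Of 17 hypoxia and glycolysis genes, 4 rose and 10 fell, 5 and 10 adjusted over the list alone (median -0.19, range -0.24 to -0.11, adjusted p 0.29), with P4HA1 (-1.73 ± 0.0667) and NDRG1 (-1.21 ± 0.0523, chosen after its values were seen) falling and EGLN3 (1.90 ± 0.0881) rising.

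Markers of other cell types and of immune signalling also failed to pass as lists under shEED-1. Of 15 interferon-stimulated genes, 4 rose and 5 fell (median -0.062, range -0.16 to -0.00298, adjusted p 0.61), with a fall of CMPK2 (-1.16 ± 0.0452), a rise of ISG15 (0.82 ± 0.0537) and BST2 at least 4.01-fold lower. Of 10 antigen presentation genes, 3 rose and 2 fell (median 0.025, range -0.13 to 0.12, adjusted p 0.98). B2M, the light chain of class I molecules, fell (-0.56 ± 0.0394). Of 5 Schwann cell and melanocyte markers, 0 rose and 2 fell (median -0.019, range -0.24 to 0.00484, adjusted p 0.55). Of 14 fibroblast and matrix markers, 4 rose and 4 fell (median 0.049, range -0.086 to 0.13, adjusted p 0.98), with a mean of -0.079 and the test pointing up. Of the blood and endothelial markers only CD14 (0.33, adjusted p 0.151; it passed without control replicate 2, 0.51) and CD68 (-0.11, adjusted p 0.404) were measured, too few to test. Without a filter on dim probes p53 targets (adjusted p 0.0016) and unfolded protein response genes (adjusted p 0.012) passed. Counts adjusted over the list alone equalled those over all genes except where given. With an estimated correlation 1 of the 23 lists passed under shEED-1, the synaptic genes, against 6 with the preset one, and fry, which tests whether a list's genes move one way and does not set them against other genes, called 17.

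The comparison of shEED-2 with the same control asked the question for the second hairpin. Here catecholamine genes, neurotrophin and GDNF receptors and cholesterol synthesis genes fell, while the neuronal and synaptic lists did not pass. DBH fell by 2.08 (SE 0.0497, n = 3 against 4 arrays, limma adjusted p 2.09e-08), and the GDNF receptors RET and GFRA2 by 2.04 (SE 0.0485) and 2.26 (SE 0.0481). Metallothioneins, which bind zinc and copper, rose steeply: MT1F by 3.83 ± 0.0552, MT1M by 3.75 ± 0.115 and MT1E by 3.72 ± 0.0576. On other MT1E probes the rises were 3.55 and 2.11. In total 7096 genes passed (39.9%), 3172 higher and 3924 lower, with a median absolute change of 0.33, and 408 with at least a 2-fold change, 188 higher and 220 lower. The share that was higher depended on the scaling: 44.7% here, 74.3% (5108 higher, 1771 lower) with the median shift, which moved the median of all genes from -0.029 to 0.095, and 34.2% (2493 higher, 4798 lower) with the spike-in shift. On slide 1 alone 5273 passed, and 5783 with slide as a block.

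Of 15 catecholamine and chromaffin genes, 11 fell, the transporter SLC6A2 rose and 3 did not pass (2 rose and 11 fell adjusted over the list alone; median -0.37, adjusted p 0.00097; adjusted p = 0.049 with an estimated correlation). DBH, CYB561 (-1.03 ± 0.105) and MAOA (-1.13 ± 0.0579) fell, as did the secretory granule genes CHGB (-0.58 ± 0.0645), SCG2 (-0.55 ± 0.0514) and SCG3 (-1.22 ± 0.0554) and the decarboxylase DDC (-0.38 ± 0.0505), which makes dopamine. TH, the rate-limiting enzyme of the pathway, was at -0.17 (adjusted p 0.279). Of 8 neurotrophin and GDNF receptors, 5 fell, none rose and 3 did not pass (median -1, adjusted p 0.00097; adjusted p = 0.049 with an estimated correlation). Among them were RET, NTRK3 (-2.25 ± 0.146), GFRA2 (-2.26 ± 0.0481) and NTRK2 (-0.95 ± 0.121), while NGFR was at -0.17 (adjusted p 0.435; it passed with normexp). GFRA1 did not pass on its brightest probe (-0.12) but fell on another (-1.23). Other lists held 2 of the 8 genes, and slide 1 medians were -0.36 and -1. With normexp NTRK3 (-0.86) and NTRK2 (-0.42) changed less, and the receptor median was -0.43. SLC6A2, SCG2, SCG3, DDC, TH and GFRA1 were chosen after their values were seen.

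Of 23 cholesterol synthesis genes, 20 fell, none rose and 3 did not pass (median -0.33, adjusted p 3e-06; adjusted p = 0.015 with an estimated correlation). The squalene enzymes FDFT1 (-0.77 ± 0.0458) and SQLE (-0.63 ± 0.0838), ACAT2 (-0.49 ± 0.0523) and LSS (-0.40 ± 0.0441, chosen after its values were seen) were among them, LSS not passing on another probe (-0.13). The cholesterol median was -0.21 with the median shift. Of 34 cell cycle genes, 16 fell, CCNE1 (0.58 ± 0.0601) and CDT1 (0.13 ± 0.0442) rose and 16 did not pass (median -0.14, adjusted p 0.002; adjusted p = 0.19 with an estimated correlation). RRM2, which makes deoxynucleotides, fell by 1.07 (SE 0.0529) and TOP2A by 0.52 (SE 0.0431). The cell cycle call was lost with the median shift (median -0.02, adjusted p 0.068) and normexp (-0.078, adjusted p 0.28), and the median was -0.08 with quantile normalization. CDT1, chosen after its values were seen, lost its call without any of 8 arrays (0.10 to 0.14), namely control replicate 2, control replicate 3, control replicate 4, shEED-1 replicate 1, shEED-1 replicate 2, shEED-2 replicate 1, shEED-2 replicate 2 and shEED-2 replicate 3. Slide 1 medians were -0.36 for cholesterol synthesis and -0.17 for the cell cycle.

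The neuronal lists did not pass under shEED-2. Of 23 synaptic genes, 9 rose and 4 fell, 10 and 5 adjusted over the list alone (median 0.015, range -0.029 to 0.19, adjusted p 0.2). Of 25 neuronal structure genes, 10 rose and 4 fell (median 0.091, range 0.023 to 0.21, adjusted p 0.16). STMN4 (2.97 ± 0.0912), ENO2 (0.61 ± 0.0629), SYT11 (0.49 ± 0.044) and RAB3A (0.44 ± 0.0527) rose. ELAVL4 fell (-1.09 ± 0.0579), DCX was at -0.05 (adjusted p 0.514) and SYP, a vesicle membrane gene, at -0.02 (adjusted p 0.858). The neuronal structure list passed, upward, with quantile normalization (adjusted p 0.047), normexp (0.0063) and no filter on dim probes (0.0057). Of 9 genes repressed by EZH2, 3 rose and 1 fell (median 0.092, range 0.028 to 0.22, adjusted p 0.51). CDKN1C (0.39 ± 0.0716), KLF4 (0.61 ± 0.142) and CLU (0.27 ± 0.0942) rose. CLU's call was lost without any of 8 arrays (0.21 to 0.28), namely control replicate 2, control replicate 3, control replicate 4, shEED-1 replicate 1, shEED-1 replicate 2, shEED-2 replicate 1, shEED-2 replicate 2 and shEED-2 replicate 3, and normexp ended KLF4's (0.06). Of 19 mesenchymal markers, 8 rose and 5 fell (median 0.066, range -0.021 to 0.19, adjusted p 0.33). LOXL2, a collagen cross-linking enzyme (1.51 ± 0.0757), and PRRX1 (1.39 ± 0.0537) rose, and SPARC (-1.32 ± 0.0619) and FOSL2 (-1.15 ± 0.0576) fell. DCX, SYP, ELAVL4, LOXL2 and PRRX1 were chosen after their values were seen.

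The remaining lists did not pass under shEED-2 either. Of 24 HOX genes, 3 rose and 7 fell, 6 and 8 adjusted over the list alone (median -0.015, range -0.11 to 0.11, adjusted p 0.51). HOXC13 was at least 1.54-fold lower, and HOXD8 (-0.76 ± 0.0658), HOXD10 (-0.64 ± 0.0756) and HOXD11 (-0.78 ± 0.068) fell, the last pair chosen after their values were seen. Of 45 non-HOX regulators bound by Polycomb, 18 rose and 12 fell, 18 and 13 adjusted over the list alone (median 0.09, range -0.1 to 0.21, adjusted p 0.22), with rises of NEUROD1 (0.78 ± 0.0458) and LHX1 (0.68 ± 0.0743) and a fall of FOXF1 (-0.73 ± 0.0427). Of 21 PRC1 genes, 3 rose and 3 fell, 2 and 3 adjusted over the list alone (median 0.071, range 0.028 to 0.2, adjusted p 0.33), CBX7 among the former (0.85 ± 0.0734 on its brightest probe, while its other probe fell, -0.34; 0.26 with the mean of both). Of 23 adrenergic regulators, 8 rose and 4 fell (median 0.095, range 0.051 to 0.22, adjusted p 0.2). MYCN was at -0.02 (adjusted p 0.786). Of 29 MYC and MYCN targets, 1 rose and 9 fell (median -0.11, range -0.15 to 0.016, adjusted p 0.2). Of 7 CDK inhibitors, 2 rose and 0 fell (median 0.086, range 0.043 to 0.21, adjusted p 0.2). Of 25 p53 targets, 9 rose and 7 fell (median 0.029, range -0.028 to 0.15, adjusted p 0.42). BBC3 (1.28 ± 0.0567), BTG2 (0.59 ± 0.0462) and TP53INP1 (1.19 ± 0.0765) rose and MDM2 fell (-0.30 ± 0.0403). On other probes MDM2 was at -0.26, which passed, and at -0.17 and 0.09, which did not. Of 21 BCL2 family and caspase genes, 10 rose and 5 fell, 12 and 5 adjusted over the list alone (median 0.19, range 0.079 to 0.32, adjusted p 0.1), with rises of CASP9 (0.55 ± 0.0794) and BMF (0.85 ± 0.0713, chosen after its values were seen). Adrenergic regulators and BCL2 family and caspase genes passed, pointing up, with normexp (adjusted p 0.024 and 0.022) and without a filter on dim probes (0.016 and 0.0099). Without the filter synaptic genes (adjusted p 0.018) and CDK inhibitors (0.028) also passed, pointing up.

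Under shEED-2, of 23 unfolded protein and integrated stress response genes, 5 rose and 4 fell (median 0.00086, range -0.043 to 0.12, adjusted p 0.35). Of 17 hypoxia and glycolysis genes, 7 rose and 4 fell, 8 and 4 adjusted over the list alone (median 0.17, range 0.13 to 0.29, adjusted p 0.22). The vasodilator peptide gene ADM fell (-1.27 ± 0.0638) and VEGFA, the endothelial growth factor, rose (0.66 ± 0.0439, chosen after its values were seen). Of 15 interferon-stimulated genes, 4 rose and 5 fell, 5 and 5 adjusted over the list alone (median -0.0068, range -0.061 to 0.12, adjusted p 0.87); their mean was -0.15 and the test pointed up. ISG15 (0.85 ± 0.0537) and IRF7 (0.29 ± 0.0388, chosen after its values were seen) rose and CMPK2 fell (-0.79 ± 0.0452). Of 10 antigen presentation genes, 0 rose and 2 fell (median -0.067, range -0.17 to 0.057, adjusted p 0.41). Of 5 Schwann cell and melanocyte markers, 0 rose and 2 fell, 0 and 4 adjusted over the list alone (median -0.53, range -0.61 to -0.18, adjusted p 0.12). Of 14 fibroblast and matrix markers, 5 rose and 3 fell, 6 and 3 adjusted over the list alone (median 0.11, range 0.043 to 0.23, adjusted p 0.25), with falls of ACTA2 (-0.90 ± 0.0551) and PDGFRB (-0.43 ± 0.0767). The macrophage marker CD68 fell (-0.82 ± 0.104), and CD14 rose (0.66 ± 0.181), a call lost without shEED-2 replicate 1 (0.56) and on slide 1 alone (0.41). With an estimated correlation 3 of the 23 lists passed, against 4 with the preset one, and fry called 19.

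**Figure D2:**
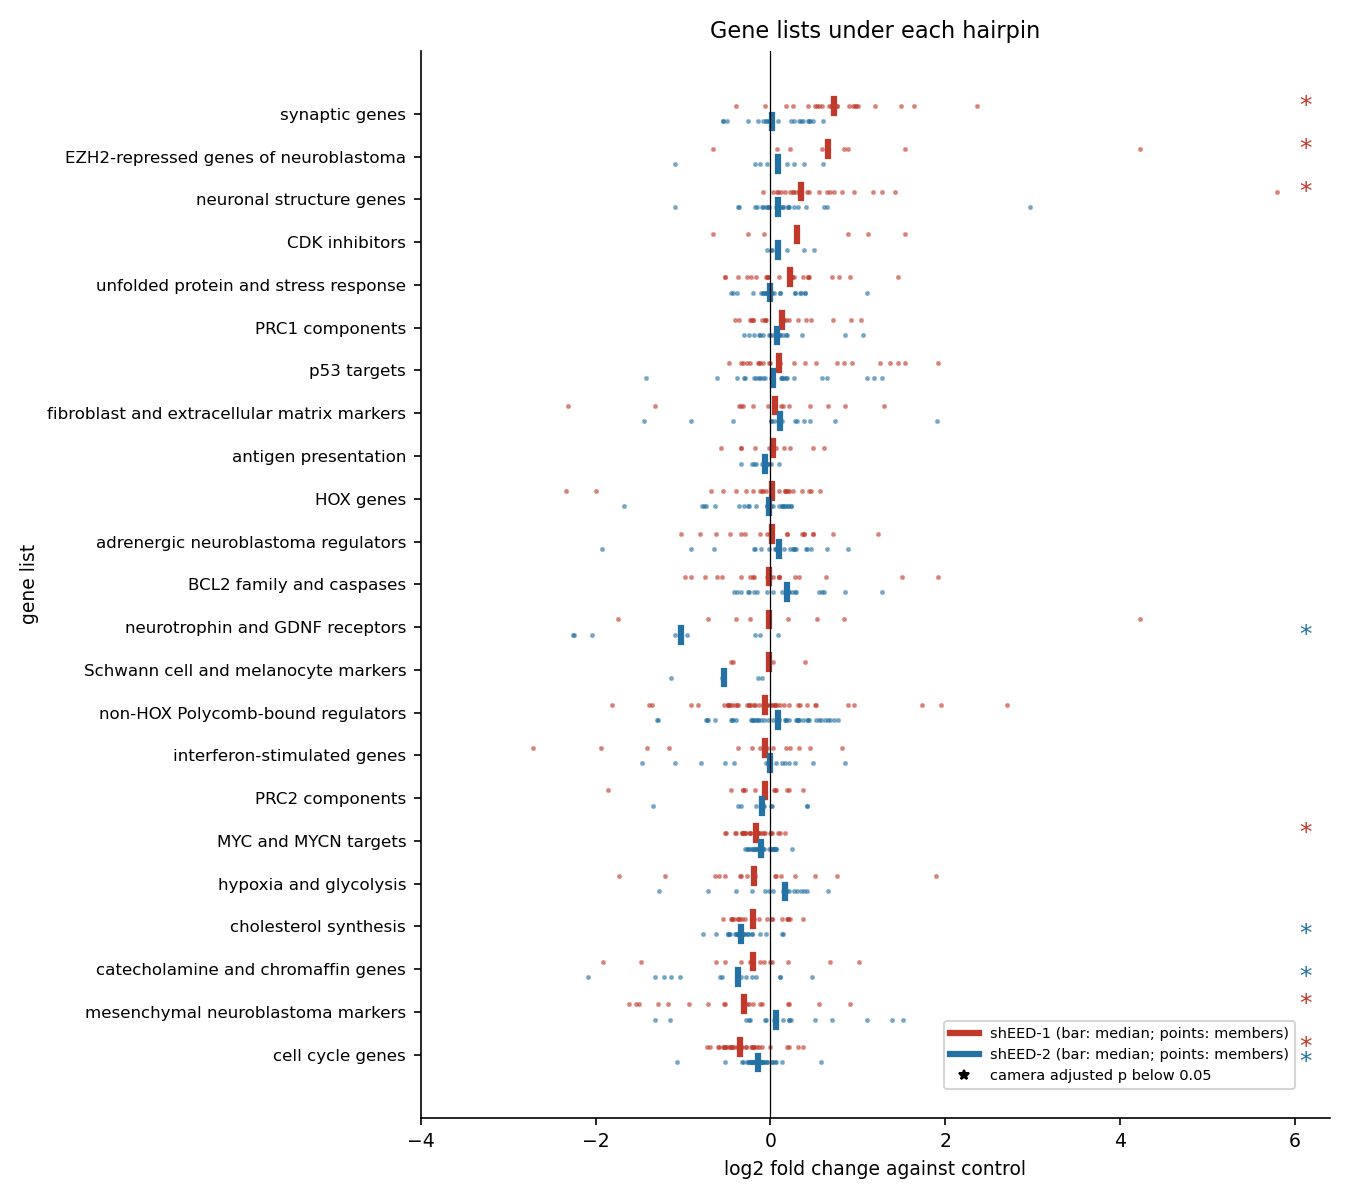
Log2 fold change against control of the measured members of 23 gene lists (points) and their medians (bars) for shEED-1 (red) and shEED-2 (blue); a star marks a camera adjusted p below 0.05. Synaptic genes had medians of 0.73 and 0.015, and neurotrophin and GDNF receptors -0.018 and -1; the signs of the 0.015 and the -0.018 turned in some alternatives.

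The genes changed the same way by both hairpins were asked for because a shared change is less open to effects of a single hairpin sequence. The control was an empty vector, so an effect of expressing any hairpin would be shared too and cannot be told from EED loss. Largest among the rises were STMN4 (5.80 and 2.97, SE 0.0912), SH2D3C, an adaptor of SH2 domains (4.33 and 2.23, SE 0.0642), TTC9B (3.97 and 1.15, SE 0.0747), the neuronal repressor SCRT1 (3.40 and 1.68, SE 0.125), the tau kinase TTBK1 (3.32 and 1.05, SE 0.0707) and the metallothioneins MT1F (1.12 and 3.83, SE 0.0552) and MT1M (0.68 and 3.75, SE 0.115). HID1 (3.49 and 1.96, SE 0.285), PTH1R (3.61 and 1.45, SE 0.19) and JCAD (2.66 and 1.97, SE 0.117) rose too, with 3, 3 and 1 of the 4 control arrays well above background. LRP1B was at least 1.57-fold and 2.83-fold higher and MAMLD1 at least 5.02-fold and 2.28-fold higher, bounds given where a group was not well above background on any array. Such a bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. With normexp the call of LRP1B under shEED-1 (0.10) and of MAMLD1 under shEED-2 (0.12) was lost, and STMN4 (3.63 and 1.20), HID1 (1.56 and 0.57) and JCAD (0.56 and 0.27) changed less.

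Largest among the falls were LIX1 (-3.50 and -1.24, SE 0.049), the BMP receptor ACVRL1 (-2.52 and -2.21, SE 0.065), TMEM98 (-2.42 and -2.26, SE 0.171), the homeobox gene LBX2 (-2.91 and -1.58, SE 0.0644), GCHFR, which regulates the synthesis of the cofactor of tyrosine hydroxylase (-2.31 and -2.13, SE 0.079), and the ammonium transporter RHBG (-1.87 and -2.42, SE 0.11). DCDC1 fell as well (-3.77 and -3.00, SE 0.358), with 1 of 3 shEED-1 arrays well above background. The liver-secreted protein gene FGL1 was at least 5.19-fold and 4.77-fold lower, the crystallin CRYGC at least 2.99-fold and 2.85-fold and the keratin KRT19 at least 2.72-fold and 2.49-fold. The transporter ABCC3 was at least 6.04-fold lower under shEED-1 and fell under shEED-2 (-1.11 ± 0.174), and so did BST2, at least 4.01-fold and -1.47 ± 0.178. From the lists, DBH (-1.92 and -2.08, SE 0.0497), RET (-1.74 and -2.04, SE 0.0485), SPARC (-1.53 and -1.32, SE 0.0619) and CYB561 (-1.48 and -1.03, SE 0.105) fell under both, and BBC3 (1.92 and 1.28, SE 0.0567), TP53INP1 (1.25 and 1.19, SE 0.0765) and NEUROD1 (1.96 and 0.78, SE 0.0458) rose under both. With normexp, falls of TMEM98 (-1.05 and -1.01), LBX2 (-1.53 and -1.02) and DCDC1 (-1.25 and -1.17) were smaller.

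In total 3895 genes passed in the same direction under both hairpins, 1828 higher and 2067 lower, 88 and 75 of them by at least 2-fold in each. The change was larger under shEED-1 for 2667 of them (68.5%), and the median ratio of shEED-2's change to shEED-1's was 0.75. By list, both hairpins raised 10 of 25 neuronal structure genes, 9 of 23 synaptic genes and 3 of 9 genes repressed by EZH2. Both lowered 14 of 34 cell cycle genes, 12 of 23 cholesterol synthesis genes, 7 of 29 MYC and MYCN targets, 5 of 15 catecholamine genes, 5 of 19 mesenchymal markers and 4 of 8 neurotrophin and GDNF receptors. Both hairpins were set against the same control arrays. The product of the single counts over the genes tested gave 916 higher and 1163 lower, and 100 simulations of unchanged groups with shared controls gave a median of 0 and at most 1. The simulations held no changed gene, so a count near 0 was fixed in advance. They do not measure what shared controls add to the 3895. With 6 splits of the controls, 2 for each hairpin, 2618 to 2831 genes passed the same way and 772 to 923 in opposite ways. Across genes, the correlation between the hairpins' changes was 0.378, and 0.318 to 0.328 with split controls. In the simulations it was 0.43, from the noise of shared controls alone, and is no yardstick for the 0.378. The covariance was 0.0775 in the data, 0.0075 in the simulations and 0.0681 to 0.07 with split controls. Of those shared genes 46.9% were higher, 74% (2539 higher, 892 lower) with the median shift and 36.4% (1453 higher, 2540 lower) with the spike-in shift. On slide 1 alone 2949 were shared, and 3210 with slide as a block.

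**Figure D3:**
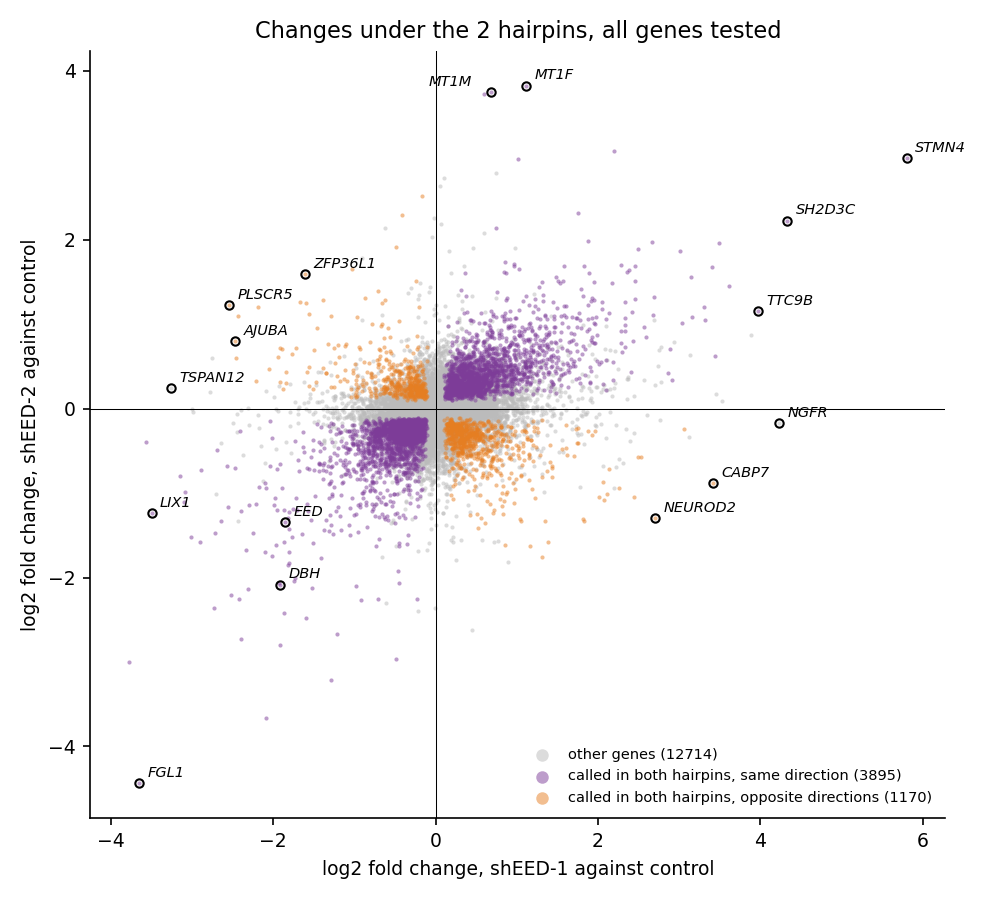
Log2 fold change against control under shEED-1 (horizontal) and shEED-2 (vertical) for each gene tested; colours mark genes that passed under both hairpins in the same (3895) or opposite (1170) directions and grey all others, and named genes are circled. Metallothioneins such as MT1F and MT1M lie high on the vertical axis (3.83 and 3.75) and NGFR far right (4.23) near 0 vertically.

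The direct comparison of shEED-2 with shEED-1 asked where the hairpins differed. Among single genes higher under shEED-1 were NGFR by -4.40 ± 0.175 as shEED-2 minus shEED-1 (n = 3 against 3 arrays, limma adjusted p 1.33e-07), the calcium sensor gene CABP7 by -4.30 ± 0.167, the neurogenic factor NEUROD2 by -4.0 ± 0.104 and the neuronal calcium sensor HPCA by -3.16 ± 0.0682. Metallothioneins MT1E (3.12 ± 0.0616) and MT2A (2.71 ± 0.0753, chosen after its values were seen) were higher under shEED-2, as were TSPAN12 (3.50 ± 0.11), AJUBA, a scaffold of cell junctions (3.27 ± 0.105), and ZFP36L1, which destabilises messenger RNAs (3.20 ± 0.105). On 1 other MT1E probe the hairpins lay closer, with changes against control of 1.30 under shEED-1 and 2.11 under shEED-2. Another MT1E probe had 0.44 and 3.55. In total 9528 genes differed (53.6%), 4535 higher and 4993 lower under shEED-2, 1064 of them at least 2-fold (349 and 715). The share higher was 47.6%, and 62.4% (5811 higher, 3504 lower) with the median shift. On slide 1 alone 9405 differed, and 9682 with slide as a block.

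Of the genes, 1170 passed under both hairpins in opposite directions, 705 higher under shEED-1 and lower under shEED-2 and 465 the other way, where the product of the single counts gave 2073. MDM2 (0.27 and -0.30, SE 0.0403, but not passing under shEED-2 on other probes at -0.17 and 0.09), CABP7 (3.42 and -0.88, SE 0.156), NEUROD2 (2.71 and -1.29, SE 0.0975), PLAC9 (2.44 and -1.05, SE 0.0522) and HPCA (1.82 and -1.33, SE 0.0638) rose under shEED-1 and fell under shEED-2. The scramblase gene PLSCR5 (-2.54 and 1.23, SE 0.0937), AJUBA (-2.47 and 0.80, SE 0.098), ZFP36L1 (-1.61 and 1.59, SE 0.0983), PRRX1 (-0.71 and 1.39, SE 0.0537), FOXC1 (-1.35 and 0.42, SE 0.0743) and NDRG1 (-1.21 and 0.39, SE 0.0523) did the reverse; PRRX1, FOXC1 and NDRG1 were chosen after their values were seen. TYRP1, a melanin synthesis gene, rose under shEED-1 (3.46 ± 0.138) and was at 0.17 under shEED-2 (adjusted p 0.351; difference -3.29 ± 0.147). GNG3, a G protein subunit of neurons, was at least 4.24-fold lower under shEED-2 than under shEED-1, and TMEM229B at least 2.71-fold. SOX6, a transcription factor, was at least 6.16-fold higher under shEED-2 and SNORA79, a small nucleolar RNA, at least 4.17-fold. BNC2 was at least 2.92-fold higher under shEED-2. Without control replicate 3, on slide 1 alone or without the filter, another BNC2 probe was the brightest, and it did not pass (0.54, adjusted p 0.062 without that array).

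As a group, 21 of 23 synaptic genes were lower under shEED-2 than under shEED-1, none was higher and 2 did not pass (median -0.5, adjusted p 1.3e-07; adjusted p = 0.0082 with an estimated correlation). The neuronal structure genes followed, with 16 of 25 lower, none higher and 9 not passing (median -0.42, adjusted p 4.4e-05; adjusted p = 0.22 with an estimated correlation). Examples were RAB3A (-1.21 ± 0.0563), SYP (-0.78 ± 0.0793), MAPT (-0.96 ± 0.0451) and SNAP25, of the vesicle fusion machinery (-0.81 ± 0.0548). Of 8 neurotrophin and GDNF receptors, 7 were lower and none higher (median -1.1, adjusted p 0.00035; adjusted p = 0.045 with an estimated correlation), with GFRA2 at -2.02 ± 0.0515 and NTRK3 at -1.54 ± 0.156. Of 34 cell cycle genes, 20 were higher and 3 lower under shEED-2 (median 0.23, adjusted p 0.0034; adjusted p = 0.22 with an estimated correlation): AURKA by 0.51 ± 0.0616, but RRM2 (-0.84 ± 0.0565), E2F1 (-0.35 ± 0.0559) and E2F2 (-0.30 ± 0.076) were lower. Of 19 mesenchymal markers, 11 were higher and 4 lower (median 0.33, adjusted p 0.021; adjusted p = 0.23 with an estimated correlation), with LOXL2 (1.75 ± 0.0809), SOX9 (1.68 ± 0.168) and SNAI2 (0.90 ± 0.0615) higher. That call was lost without shEED-1 replicate 1 (median 0.27, adjusted p 0.052) and with every probe tested (0.21, adjusted p 0.19). With normexp the medians of receptors and mesenchymal markers were -0.54 and 0.21. Medians of these 5 lists on slide 1 alone and with slide as a block (-0.5, -0.42, -1.1, 0.23 and 0.33) equalled those above by construction. Every knockdown array was on slide 1, so these settings do not test the medians. SYP, SNAP25, E2F1, E2F2, LOXL2 and SOX9 were chosen after their values were seen.

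The other lists did not pass in this comparison. Of 9 genes repressed by EZH2, 1 was higher and 6 lower (median -0.39, range -0.44 to -0.24, adjusted p 0.073). Of 17 hypoxia and glycolysis genes, 11 were higher and 5 lower (median 0.31, adjusted p 0.073). Of 25 p53 targets, 4 were higher and 13 lower (median -0.2, range -0.23 to -0.096, adjusted p 0.073). Of 29 MYC and MYCN targets, 10 were higher and 3 lower, 10 and 2 adjusted over the list alone (median 0.11, range 0.05 to 0.21, adjusted p 0.073). Of 15 catecholamine genes, 3 were higher and 9 lower (median -0.18, range -0.22 to -0.076, adjusted p 0.1). Of 23 cholesterol synthesis genes, 2 were higher and 10 lower (median -0.18, range -0.21 to -0.077, adjusted p 0.1), and this list passed with quantile normalization (adjusted p 0.042) and no filter on dim probes (0.0067). Of 24 HOX genes, 6 were higher and 7 lower (median -0.027, range -0.062 to 0.073, adjusted p 0.82). Of 45 non-HOX regulators bound by Polycomb, 17 were higher and 10 lower (median 0.1, range 0.051 to 0.2, adjusted p 0.28). Of 23 adrenergic regulators, 7 were higher and 7 lower (median -0.041, range -0.08 to 0.059, adjusted p 0.77); their mean was -0.0056 and the test pointed up. Of 12 PRC2 genes, 4 were higher and 1 lower (median 0.088, range 0.039 to 0.19, adjusted p 0.38). Of 21 PRC1 genes, 3 were higher and 5 lower (median -0.071, range -0.11 to 0.029, adjusted p 0.79). Of 21 BCL2 family and caspase genes, 7 were higher and 5 lower (median 0.036, range 0.0067 to 0.14, adjusted p 0.34). Of 7 CDK inhibitors, 3 were higher and 4 lower (median -0.29, range -0.4 to 0.17, adjusted p 0.77). Of 23 unfolded protein and integrated stress response genes, 5 were higher and 9 lower, 6 and 9 adjusted over the list alone (median -0.096, range -0.15 to 0.0038, adjusted p 0.41). Of 15 interferon-stimulated genes, 5 were higher and 2 lower (median 0.055, range 0.022 to 0.15, adjusted p 0.34). Of 10 antigen presentation genes, 3 were higher and 5 lower, 3 and 6 adjusted over the list alone (median -0.18, range -0.22 to -0.068, adjusted p 0.77). Of 5 Schwann cell and melanocyte markers, 2 were higher and 2 lower, 2 and 3 adjusted over the list alone (median -0.56, range -0.69 to 0.021, adjusted p 0.79). Of 14 fibroblast and matrix markers, 5 were higher and 4 lower (median 0.11, range -0.00949 to 0.21, adjusted p 0.77). MYC and MYCN targets passed with the median shift (adjusted p 0.035), the mean of a gene's probes (0.046), every probe tested (0.0087) and no filter (0.027). Hypoxia and glycolysis genes passed with every probe tested (adjusted p 0.031) and no filter (0.025), and without the filter so did the genes repressed by EZH2 (0.003), catecholamine genes (0.014) and p53 targets (0.0023). With an estimated correlation 2 of the 23 lists passed, against 5 with the preset one, and fry called 19.

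**Figure D4:**
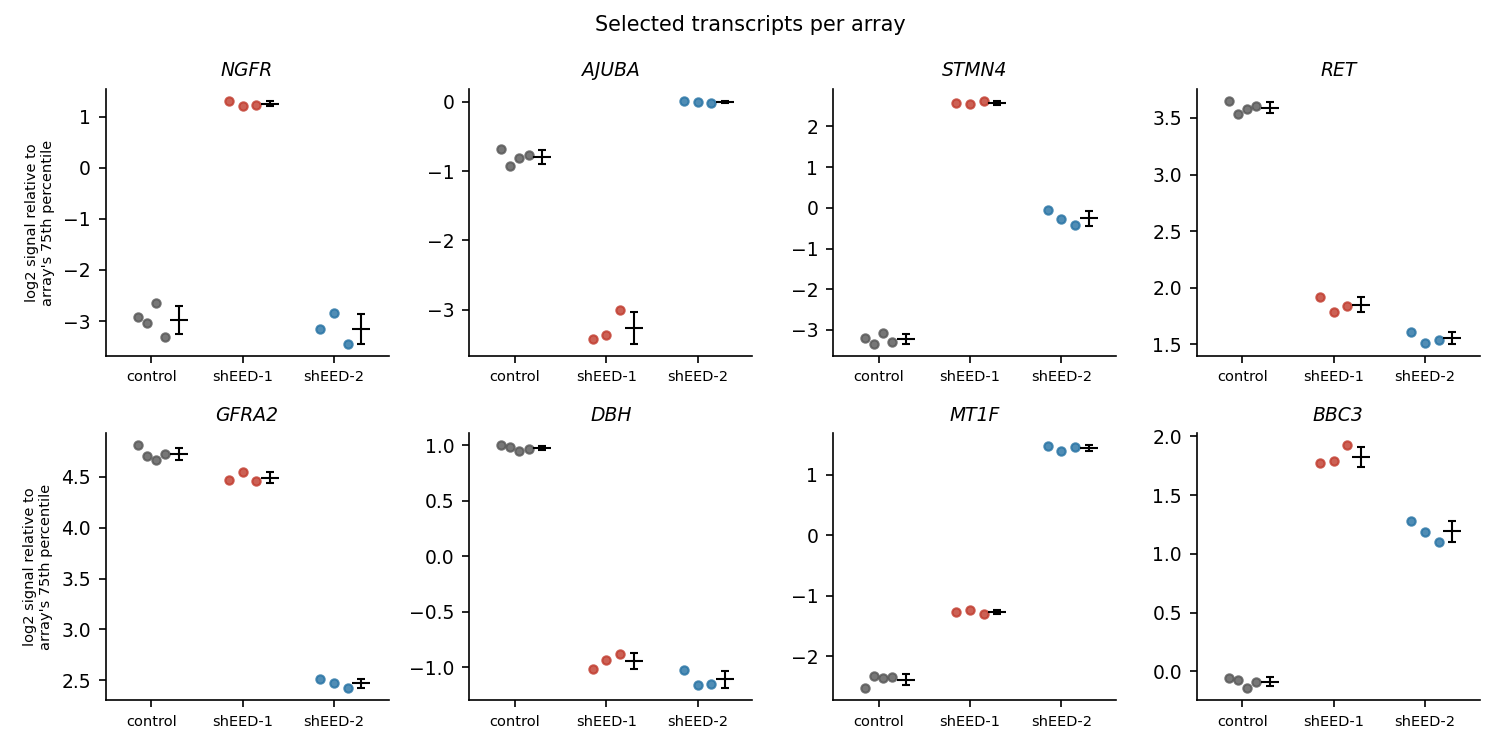
Log2 signal relative to the array's 75th percentile of 8 transcripts in control (n = 4), shEED-1 (n = 3) and shEED-2 (n = 3) arrays; points are arrays, and the bar beside them is the mean ± SD. NGFR was higher under shEED-1 alone among the 2 hairpins (4.23 against -0.17), DBH was lower under both (-1.92 and -2.08), and MT1F was highest under shEED-2 (3.83 against 1.12).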

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

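Of the tests in this part, those of a response in proportion to the loss of EED and of signal between paralogous metallothionein probes, the test of the metallothioneins as a list, and the normexp and slide 1 settings were chosen only after the results were seen. REST, SLC30A1, MTF1 and HMOX1 were not named by the rule, and were examined to address patterns seen in these data. Of the 180 named genes, 5 had 1 control array apart from the other 3 by Dixon's test, where chance alone gives about 9. These were RBBP4 in control 2 (4.33; others 4.56 to 4.6), PTH1R in control 1 (-4.25; others -3.48 to -3.38), DCDC1 in control 1 (-1.16; others -1.03 to -1.01), PCGF3 in control 2 (-4.32; others -3.55 to -3.42) and CCNE1 in control 1 (3.18; others 3.02 to 3.04).

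The hairpins differed, by the direct test, in 5 gene lists: median differences, shEED-2 minus shEED-1, were 0.33 for mesenchymal markers, -0.42 for neuronal structure genes, -0.5 for synaptic genes, -1.1 for neurotrophin and GDNF receptors and 0.23 for cell cycle genes. With an estimated correlation only the synaptic genes and the receptors of these passed, at an adjusted p of 0.0082 and 0.045, and the other 3 had 0.23, 0.22 and 0.22. In all, 1170 genes passed under both hairpins in opposite directions and differed between them. Among named genes with opposed changes, the difference was positive for PLSCR5 (3.77), AJUBA (3.27), ZFP36L1 (3.2), SMAD3 (1.74), PRRX1 (2.11), LOXL2 (1.75), FOXC1 (1.78), CASP6 (1.17), BMF (1.4), NDRG1 (1.6) and MT2A (2.71). It was negative for MDM2 (-0.572), CABP7 (-4.3), NEUROD2 (-4), PLAC9 (-3.49), HPCA (-3.16), SNAP25 (-0.806), L1CAM (-1.54), SCG2 (-1.56), DHCR7 (-0.533), LSS (-0.626), HOXA9 (-0.921), HOXD10 (-1.08), HOXD11 (-1.04) and MT3 (-0.436). Only bounds can be given for BNC2 (at least 2.92-fold higher under shEED-2), SNORA79 (at least 4.17-fold higher) and TMEM229B (at least 2.71-fold lower), because 1 hairpin was not well above background on any array. BNC2 was represented by another probe without control replicate 3, and that probe was at -0.74 under shEED-2 with a difference of 0.54 (adjusted p 0.062), so the 2 probes gave different values. SNORA79's call under shEED-2 was lost without any of 7 arrays (1.09 to 1.31), namely the 4 control and 3 shEED-2 arrays. TMEM229B was well above background on no control or shEED-2 array, so no fall under shEED-2 is claimed. HOXA9 did not pass under either hairpin on another probe (-0.09 and -0.17), nor LSS under shEED-2 (-0.13). MDM2 did not pass under shEED-2 on other probes at -0.17 and 0.09.

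Further calls behind these opposed changes were lost when an array was left out: SMAD3 under shEED-2 without any of control replicate 2, control replicate 3, shEED-2 replicate 1 and shEED-2 replicate 2 (0.18 to 0.22), LOXL2 under shEED-1 without any of control replicate 4, shEED-1 replicate 1 and shEED-1 replicate 2 (-0.20), L1CAM under shEED-2 without shEED-2 replicate 3 (-0.31), DHCR7 under shEED-1 without any of control replicate 2, control replicate 4, shEED-1 replicate 1 and shEED-1 replicate 3 (0.14 to 0.21) and MT3 under shEED-1 without any of control replicate 1, control replicate 2, control replicate 3, shEED-1 replicate 1 and shEED-1 replicate 2 (0.12 to 0.17).

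No other split of the arrays gave as many genes as the real one. Under shEED-1 the real split gave 10403 (1 of 35 splits as large, highest other 11). Under shEED-2 it gave 7096 (1 of 35, highest other 5), and under both 3895 (1 of 100 drawn, highest other 9). Splits that mix the groups put the difference between groups into the residual spread, so they call few genes whatever its cause. The replicates may not be separate cultures, so chance differences between cultures are not excluded. For the list counts, other splits reached the real value: 2 of 35 splits gave as many as the 6 lists under shEED-1 (highest other 6), and 3 of 35 as many as the 4 under shEED-2 (highest other 4). Those other splits set 3 of the 4 control arrays against the remaining control with the hairpin's arrays, and called 0, 5 and 3 genes; they keep most of the real contrast with its sign turned, so their lists are not a measure of chance alone. For shEED-2 against shEED-1 there were only 10 splits, too few for a share under 0.05; 1 of them, the real one, gave 9528 genes (highest other 0) and 5 lists (highest other 3).

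Neuronal structure and synaptic genes were higher under shEED-1 than under shEED-2, the former list not passing with an estimated correlation (adjusted p = 0.22 with an estimated correlation). Over all 48 measured members shEED-2's median change was 0.13 of shEED-1's (95% bootstrap interval -0.052 to 0.35), against 0.72 for EED. For these lists the ratio lay below that of EED. They were followed up because they differed between the hairpins, which favours a low ratio. The value is therefore no independent test of a response in proportion to the loss of EED transcript. Over the 3895 shared genes, kept by passing under both hairpins, the median ratio was 0.75. A threshold or steeper response stays open. With the median shift the ratio over all 48 members was 0.33 (interval 0.15 to 0.56, past the bound of 0.5 set for the test, against 0.67 for EED). Over the 42 members that passed under shEED-1 the median ratio was 0.25 (interval -0.022 to 0.38), and 0.34 (0.21 to 0.52) with the median shift. Those 42 were also kept by their call under shEED-1, which favours a low ratio further, so that value adds no support. Bootstrap intervals of medians here resample genes, which are not independent replicates, and do not measure the spread between arrays. REST, a repressor of neuronal genes in other cells, fell under shEED-1 (-1.37, interval -1.72 to -1.02, adjusted p 5.74e-05; -1.31 with slide as a block; -0.46 with normexp) and differed between hairpins by 0.97 ± 0.165, while its value under shEED-2 was -0.40 (adjusted p 0.0633; it passed without shEED-1 replicate 1 or 3, -0.41, arrays that enter there only through the pooled variance). A separate list of 20 genes repressed by REST, with no member in the lists fixed earlier, rose under shEED-1 (13 rose, 2 fell, median 0.55, interval 0.24 to 0.93, adjusted p 0.00017; adjusted p = 0.021 with an estimated correlation; 0.53 on slide 1). That list is made of neuronal genes, so any general rise of neuronal genes would raise it too. No neuronal list free of repression by REST was set beside it, so its rise cannot tell these apart. Less repression by REST may contribute under shEED-1, as a hypothesis. Whether REST fell through EED or through an off-target effect of the hairpin was not tested.

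Of 9 metallothionein genes measured, 8 rose under shEED-2 and MT3, the brain form, fell (-0.27; -0.146 and not passing with the median shift), with a median of 2.5 (2 to 3.7; adjusted p 4.4e-11, adjusted p = 0.0046 with an estimated correlation; 2.5 on slide 1), whereas 4 rose and 2 fell under shEED-1 (median 0.11). Metal exposure of the shEED-2 cultures may be the cause: SLC30A1, a zinc exporter that metal induces through the same factor, rose under shEED-2 (0.408, interval 0.292 to 0.525, adjusted p 0.00032; 0.409 with slide as a block; 0.26 with normexp). It also rose under shEED-1 (0.16, adjusted p 0.0247; lost with slide as a block, with normexp, and without any of control replicates 1 and 4 and shEED-1 replicates 1 and 2, 0.13 to 0.16), which, if real, weakens it as a marker of exposure in the shEED-2 cultures alone. The transcript of that factor, MTF1, rose under shEED-1 (0.26, limma adjusted p 0.0487) and shEED-2 (0.33, limma adjusted p 0.0268). The difference did not pass (0.07, limma adjusted p 0.602). Whether MTF1 contributed to the rise of SLC30A1 was not tested. Signal of 1 risen gene on the probes of its paralogs cannot be told apart from a rise of all 8, because probe sequences were not in the tables used. HMOX1, which oxidants and metals induce, rose more under shEED-1 (1.43) than under shEED-2 (0.32; difference -1.11 ± 0.054), and a response of the metallothioneins to the hairpin or to EED loss itself stays open and untested.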

How the results depend on the processing

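3 alternatives were chosen after the data were seen: the spike-in shift, normexp on the median signals and slide 1 alone. EED fell under both hairpins in all 25 alternatives run for genes, from -1.89 to -1.81 and -1.37 to -1.31 with 1 array left out and from -1.88 to -1.71 and -1.39 to -1.22 otherwise. Leaving out 1 array gave 9374 to 10301 genes for shEED-1, 5440 to 7207 for shEED-2, 8275 to 9557 for the difference and 3092 to 3776 for both, and 6, 4 and 4 to 5 lists. Other alternatives tested by gene without a 2-fold minimum gave 9046 to 10702, 4657 to 8265, 7592 to 10666 and 2507 to 4400 genes, and testing each of 22771 probes gave 12885, 8398, 11757 and 4569 probes; the lowest counts for shEED-2 (4657) and for both (2507) came without a filter on dim probes, and the cause was not tested. A 2-fold minimum, by construction, left 1115, 408, 1064 and 163 genes. Without the filter 9 lists passed for shEED-2 and 11 for the difference, and with quantile normalization 3 for shEED-1; the cause was not tested. An estimated correlation left 1 list for shEED-1 and 2 for the difference, and fry, which does not set a list against other genes, called 17, 19 and 19. Of 448 calls of named genes, 355 held in every alternative that kept the gene, 314 of them among the 390 calls that all 25 measured, and 4 turned direction in any: under shEED-2 MAFF with normexp (-0.0402), PMP22 with the mean of its probes (0.0348) and BNC2 without the filter (-0.396), on slide 1 alone (-0.849) and without control replicate 3 (-0.741; with 1 array left out -0.741 to 1.17), the last 3 through a switch to another probe, and under shEED-1 DDC with quantile normalization (0.00559); the cause was not tested for the other 3. With the replicate block 9249, 5394, 8832 and 2945 genes and 6, 4 and 5 lists passed and EED was at -1.81 and -1.31; equal replicate numbers did not pair arrays, since 0 of 9 such pairs correlated above 0.1 (-0.11 to 0.046). Background correction on mean signals was not run, because the tables used here lack them. With 47.1% to 49.7% of spots well above background, changes of dim genes were the least certain in size, as normexp with its offset shows (STMN4 3.63 in place of 5.80 under shEED-1).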

Other observations

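The tests of gene families, of S phase and of poly(A) capture and the slide 1 setting in this part were chosen only after the results were seen. Bootstrap intervals of medians resample genes, which are not independent replicates, and do not measure the spread between arrays. For the histones, signal shared between probes of paralogs cannot be told apart from separate falls, because probe sequences were not in the tables used. Replication-dependent histone genes, whose transcripts lack a poly(A) tail and accumulate in S phase, were lower under both hairpins. Of 59 measured, 57 fell and none rose under shEED-1 (median -0.70, 95% bootstrap interval -0.76 to -0.65; adjusted p 4.8e-19, adjusted p = 0.022 with an estimated correlation), and 46 fell and 1 rose under shEED-2 (median -0.33, interval -0.36 to -0.29; adjusted p 6.6e-13, adjusted p = 0.051 with an estimated correlation). They were lower under shEED-1 than under shEED-2 (47 differed, median difference 0.35; adjusted p 5.6e-12, adjusted p = 0.057 with an estimated correlation). Medians on slide 1 were -0.74 and -0.36, and with the median shift -0.67 and -0.21.

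Mitochondrial ribosomal protein genes also fell under shEED-1, 50 of 77 with 4 rising (median -0.25, -0.12 with quantile normalization; adjusted p 7.2e-08, adjusted p = 0.082 with an estimated correlation), while under shEED-2 23 fell and 10 rose (median -0.094, positive with the median shift; adjusted p 0.039, adjusted p = 0.4 with an estimated correlation). Clustered protocadherins, adhesion genes that mark single neurons, rose under shEED-1 in 15 of 35 and fell in 2 (median 0.2; adjusted p 0.02, adjusted p = 0.061 with an estimated correlation), with 5 rising and 4 falling under shEED-2 (median -0.052, positive with the median shift; adjusted p 0.68, adjusted p = 0.66 with an estimated correlation). Numbered ZNF genes, mostly zinc finger transcription factors, rose under shEED-2 in 113 of 365 and fell in 34 (median 0.12, 0.25 with the median shift and 0.08 with the spike-in shift; adjusted p 2.7e-05, adjusted p = 0.0058 with an estimated correlation), with 99 rising and 68 falling under shEED-1 (median 0.062; adjusted p 0.26, adjusted p = 0.21 with an estimated correlation). Slide 1 medians were -0.27 for the mitochondrial ribosomal genes and 0.2 for the protocadherins under shEED-1, and 0.12 for the ZNF genes under shEED-2.

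For the lower histone transcripts, poorer capture of RNA without a poly(A) tail was taken to lower small nuclear and nucleolar RNAs too. The bound, set after the results were seen, was 50% of the histone medians (-0.35 and -0.16). Of 284 such RNAs, 111 fell and 50 rose under shEED-1 (median -0.11, interval -0.16 to -0.074, camera adjusted p 0.02, or 0.3 with an estimated correlation). Under shEED-2, 65 fell and 16 rose (median -0.082, interval -0.11 to -0.059, positive with the median shift, camera adjusted p 0.03, or 0.3 with an estimated correlation). Both medians were smaller falls than the bound. Whether small RNAs lose as much signal as histone transcripts was not tested, so poorer capture stays a possible explanation. Less S phase could be another: 14 S-phase genes had a median of -0.21 (interval -0.33 to 0.06; -0.099 with quantile normalization) under shEED-1 and -0.12 (interval -0.24 to -0.031; -0.05 with quantile normalization and near 0 with the median shift) under shEED-2, so the intervals leave it open. Within that list 4 rose and 8 fell under shEED-1 (camera adjusted p 0.17, or 0.22 with an estimated correlation). Under shEED-2, 2 rose and 5 fell (camera adjusted p 0.088, or 0.15 with an estimated correlation). Cyclin E1 (CCNE1) was among those that rose (0.37 and 0.58, SE 0.0601) and RRM2 among those that fell (-0.23 and -1.07, SE 0.0529). A count of cells in S phase would decide it, and none was part of these data.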
